A study of Mus musculus with 2 samples.

How the data were processed

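The deposited data analysed here are 1 table of narrow peaks from the FOS ChIP-seq library of granulosa cells taken 3 h after hCG. Per the file headers, the authors passed a narrowPeak file to the annotatePeaks program of HOMER with a genome sequence and a gene annotation. Per the submitters' processing notes, Trim Galore, BWA, MACS2 2.2.7.1, deepTools 3.5.1 and the mm10 build were used. The peak threshold, the control library given to the peak caller and any filter are not given in the sources used here. The peaks come from a single library and were not pooled. Per the labels' protocols, cells were fixed with formaldehyde and sonicated before immunoprecipitation.

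The peak score is the authors' score for each peak, per the file headers the peak score of an annotated narrowPeak file. It was used to describe, rank and filter peaks within this list. The lowest score, 13, is what 10 times the negative log10 of a q-value would give at a q-value of 0.05, but the scale is not stated and no q-value is read from it. Other deposited values were the start, the end, the signed distance in bp from the peak centre to the nearest TSS, the genomic class and the nearest gene. Peak numbers run from 1 to 2374 without a gap. The files give no read counts, so the depth is unknown.

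Gene names were matched to a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, by RefSeq accession, then by symbol, then by an older symbol. All 1965 names matched. Of the peaks, 2002 had a protein-coding nearest gene and 372 a noncoding one. The background was the 21887 protein-coding genes of the table on the autosomes, X and Y, of which 1658 (7.58%) had a peak.

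All 30 gene lists, the tests, most alternatives and the rule for named genes were written before the data were examined. The lists cover the ovulatory response, its pathways, other ovarian cell types and genes of unrelated tissues. A gene was covered if it was the nearest gene of at least 1 peak. Coverage was tested with Fisher's exact test, two-sided, and adjusted by the Benjamini-Hochberg method over the 30 lists at a threshold of 0.05. As an alternative fixed at the same time, 10000 random lists of the same size were drawn, matched on 10 groups of genes with like territory, which permutes list membership within groups. Because the gene table gives no strand, a territory was measured between the midpoints of the gaps separating neighbouring gene centres, where the plan named TSSs. On simulated data with 100 lists of 20 genes per setting, drawn from the 21887 genes with coverage that rises with territory, Fisher's exact test called 88 of 100 lists with a 6-fold excess and 44 of 100 with a 3-fold excess at an unadjusted threshold. The matched lists called 93 and 47. Of unchanged lists, Fisher's exact test called 3 and the matched lists 1 of 100, but for unchanged lists from the group with the largest territories the numbers were 77 and 3. The matched fold is therefore printed beside the Fisher value for each list that passed and for the lists of ovulatory pathways, and none of the 17 lists that did not pass Fisher's exact test passed against matched lists.

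Differences in mean log2 score were tested by permutation (100000 resamples, two-sided). Chromosome counts were tested with the exact binomial test. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Genes and peaks within a library are not replicates, so each p-value describes this peak list and not the spread between animals. The search for 19 sequence motifs, AP-1 among them, the score test by motif, and the chromosome expectation from sequence length were set out before the data were examined and were not run, because no genome sequence was used here. The share of protein-coding genes, set out beside sequence length at the same time, took its place.

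The named genes are the 10 peaks with the highest score, every covered gene of the ovulatory list and of the AP-1 and MAF list, up to 4 members with the highest score in each other list, and the 10 protein-coding genes with the most peaks. The covered ovulatory genes are given in full for the 10 with the highest score. Areg, Ereg, Btc, Egr1, Vegfa and Il6 among the uncovered ovulatory genes, Fos, the 4 cAMP genes gained by host assignment, Slc45a1, Palm2 and Akap2 and the X-linked genes were chosen after their values were seen. Alternatives covered the score threshold, the distance to the TSS, the background, matching on territory and the promoter definition. Added after seeing the data were host gene assignment, peaks within 50 kb of the gene span, genes with curated transcripts, removal of the top 1% of scores, removal of genes shared with the ovulatory list and the annotated span of chromosomes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.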

Results

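The series profiled where FOS, a subunit of the AP-1 transcription factor, sits on chromatin in mouse granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle. The cells came from wild-type females 25 days old that had received PMSG, a gonadotropin that drives follicle growth, and then hCG, which acts on the luteinizing hormone receptor and starts ovulation. Cells were collected 3 h after hCG. The series has 2 libraries, of which 1 was immunoprecipitated with a FOS antibody and the other carries no antibody in its label. Values from the FOS library alone were analysed here, as the authors' list of 2374 narrow peaks with the nearest gene of each. There are no replicates, no untreated cells and no read counts, so the depth is unknown and no value below carries an error between animals. Tests compare peaks or genes within this library and describe its peak list. The purpose that the series title gives is the control of ovulatory gene expression by FOS, so the comparisons ask which genes the peaks lie nearest to, where in the genome the peaks lie, and which peaks score highest.

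Most FOS peaks lay away from promoters. Of the 2374 peaks, 1060 were in introns (44.7%, exact 95% interval 42.6 to 46.7) and 840 were intergenic (35.4%, interval 33.5 to 37.3). The authors' promoter class held 360 peaks (15.2%, interval 13.7 to 16.7), exons held 77 and transcription end sites held 37. The median distance between a peak centre and the nearest transcription start site (TSS) was 18.2 kb, and 87.1% of peaks lay within 100 kb of one. Peaks were 268 to 1114 bp wide with a median of 342 bp. The authors' peak score, a whole number that ranks peaks within this list, ran from 13 to 2234 with a median of 67. Promoter peaks had a median score of 64 against 67 for all other peaks. The difference in mean log2 score was -0.08 with a standard error of 0.05, which did not pass a two-sided permutation test (p = 0.117, 360 promoter peaks against 2014 others). The intervals cover counting error only. How much of the genome each class covers was not measured, so these shares do not show whether promoters hold more or fewer peaks than their length would give.

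Genes of the ovulatory response were the nearest gene of a FOS peak far more often than other genes. The list held 32 genes that the luteinizing hormone surge is known to induce or that ovulation needs, and 19 of them (59.4%, exact 95% interval 40.6 to 76.3) had at least 1 peak, against 7.50% of the other protein-coding genes. That was 7.92-fold more often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 9.27e-13 over 30 lists). Against random lists matched on the stretch of genome around each gene, the excess was 5.95-fold (permutation within groups of like territory, two-sided, adjusted p = 8.57e-04). The raw p behind this value, 2.00e-04, is the smallest that 10000 draws can give. Counting any peak within 50 kb of a gene, whichever gene it was assigned to, lowered the excess to 3.97-fold (23 of 32 genes against 18.1% of other genes, Fisher's exact test, adjusted p = 6.89e-10). The list shares 29 of its 32 genes with other lists tested here, so those lists are not independent of it.

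The highest score among these genes belonged to Tnfaip6, which encodes a hyaluronan-binding protein of the expanding cumulus matrix. Its promoter peak at chromosome 2, 52037794 to 52038225 (mm10), scored 355, and a further peak 18.3 kb upstream scored 62. Runx1, a transcription factor induced before ovulation, had a peak of score 129 in intron 3 of 4. Adamts1, a protease that cleaves versican in the cumulus matrix, had an intergenic peak of score 124 lying 46.8 kb downstream of its TSS. Star, the carrier of cholesterol into mitochondria, had a promoter peak of score 81 and a peak of score 104 that lay 11.0 kb downstream, inside the neighbouring gene Ash2l. Nrip1, a nuclear receptor corepressor that ovulation requires, had intergenic peaks of score 102 and 80. Hif1a, a hypoxia-response factor, had 3 upstream peaks with scores of 99, 88 and 51. Inhba, which encodes the activin and inhibin beta A subunit, had 3 peaks, of which the best (score 91) lay 724044 bp from its TSS and the others scored 69 and 44. Snap25, a vesicle fusion protein, had an intergenic peak of score 87. Ptx3, a structural component of the cumulus matrix, had a peak of score 83 inside an intron of the gene Veph1. Rgcc, a cell cycle regulator, had an intronic peak of score 77.

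The other 9 covered ovulatory genes had best scores between 31 and 74. Pgr, the progesterone receptor, had peaks of score 74 and 67 that lay 30.9 kb and 31.9 kb upstream. Ptgs2, the inducible enzyme of prostaglandin synthesis, had a promoter peak of score 44 at chromosome 1, 150099843 to 150100184. Cebpb had a promoter peak of score 70, Edn2 a peak of score 71 lying 12.6 kb upstream, Pparg intronic peaks of score 55 and 51, Has2 a peak of score 48 lying 70.0 kb upstream, and Runx2 intronic peaks of score 33, 33 and 31. Cebpa and Lhcgr, the luteinizing hormone receptor, each had a single peak of score 31. In all, 4 of the 30 peaks of this list were promoter peaks (13.3% against 15.2% of the remaining 2344 peaks, Fisher's exact test, two-sided, p = 1). The other 13 genes, among them Areg, Ereg, Btc, Egr1, Vegfa and Il6, were not the nearest gene of any peak. For 6 of the 13 a peak assigned to another gene lay within 50 kb of the gene. The nearest peak to Areg, an EGF-like growth factor, was 155 kb away, that to Ereg 96.4 kb and that to Egr1 615 kb.

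**Figure D1:**
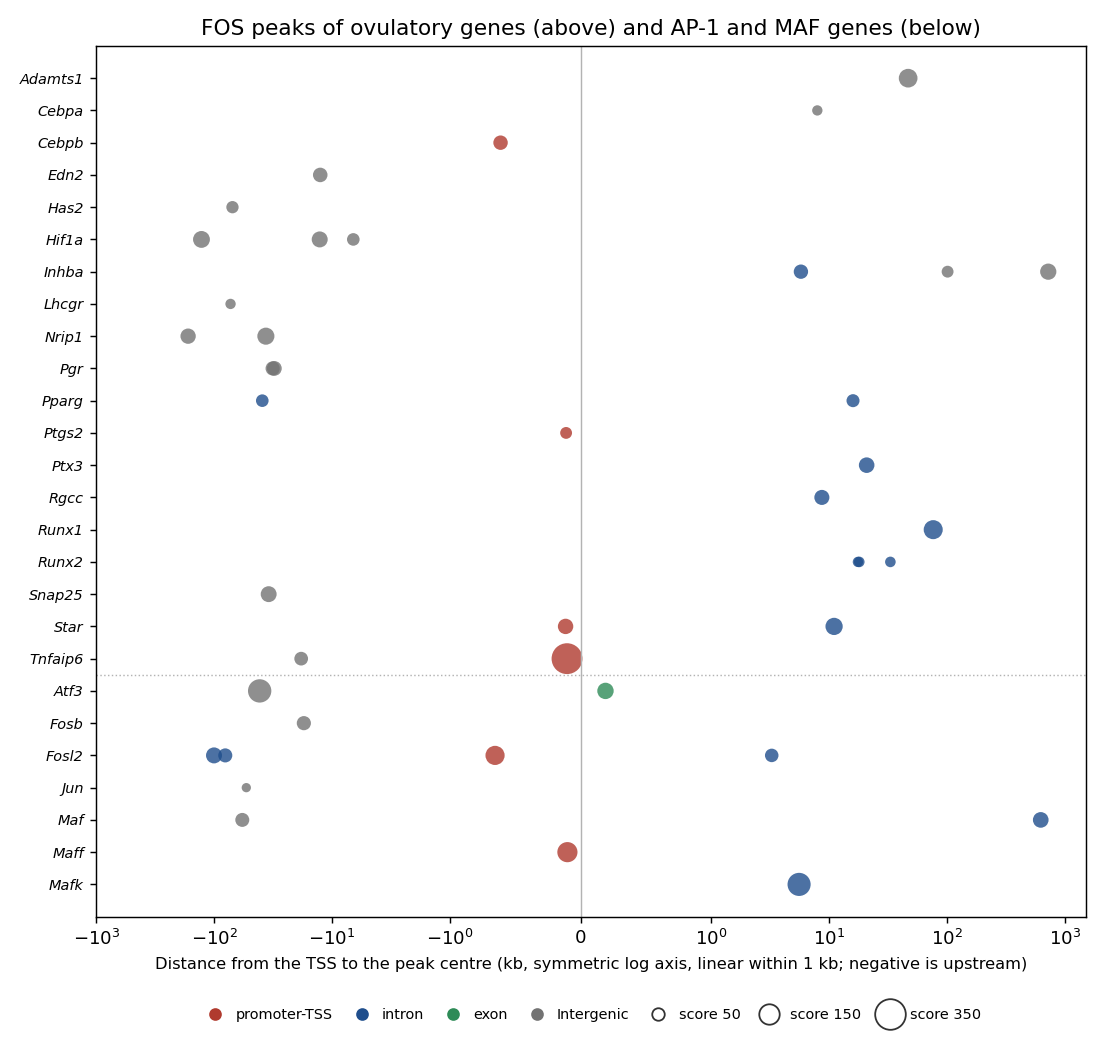
FOS peaks of the 19 ovulatory genes and 7 AP-1 and MAF genes that had any, by signed distance of the peak centre from the TSS in kb on a symmetric log axis. Each point is 1 peak, its colour is the authors' genomic class and its area rises with the peak score; Tnfaip6 carries the largest point (score 355) just upstream of its TSS, and most other points lie beyond 1 kb on either side.

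Genes that encode AP-1 and MAF proteins were also often the nearest gene of a FOS peak. Of 17 FOS, JUN, BATF, ATF3 and MAF family genes, 7 had a peak (41.2%, exact 95% interval 18.4 to 67.1), 5.45-fold more often than other genes (Fisher's exact test, adjusted p = 5.23e-04; 5.54-fold against matched random lists, adjusted p = 8.57e-04). Atf3, a stress-induced member of the ATF family, had an intergenic peak of score 199 lying 41.1 kb upstream and a peak of score 93 in exon 1 of 4. Mafk had a peak of score 195 in intron 1 of 2, and Maff had a promoter peak of score 146. Fosl2, the gene of the FOS relative FRA2, had 4 peaks, of which the promoter peak scored 131. Maf had a peak of score 84 lying 625.2 kb downstream of its TSS, inside Wwox, and 1 of score 65 lying 57.8 kb upstream. Fosb had 1 of score 67 lying 17.3 kb upstream, and Jun had 1 of score 23 lying 53.4 kb upstream. Fos itself had no peak, and the nearest was 186 kb from the gene. Counting any peak within 50 kb of a gene, whichever gene it was assigned to, ended the call for this list (2.26-fold, Fisher's exact test, adjusted p = 0.0635). Of the immediate early genes, which respond to signals without new protein synthesis, 12 of 27 had a peak (5.90-fold, Fisher's exact test, adjusted p = 1.22e-06; 4.92-fold against matched lists). Besides Atf3, the highest scores were at Csrnp1 (160), Klf4 (110) and Nr4a1 (99), with promoter peaks at Klf4 and Nr4a1. With any peak within 50 kb counted, the excess of the immediate early genes was 3.06-fold (Fisher's exact test, adjusted p = 1.1e-04). Of the 27 immediate early genes 13 are also in another list tested here, as are 5 of the 17 AP-1 and MAF genes. Atf3 is in both lists, so they are not separate results.

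With all peaks counted for their nearest gene, steroid-producing genes had the highest share of covered genes among the 30 lists. They did not lead in every alternative. A peak was assigned to 10 of the 16 steroidogenesis genes (62.5%, exact 95% interval 35.4 to 84.8), 8.29-fold more often than to other genes (Fisher's exact test, adjusted p = 3.03e-07; 7.80-fold against matched lists, adjusted p = 8.57e-04). After Star, the best scores were at Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone (92, lying 2.3 kb upstream), Nr5a2, an orphan nuclear receptor of granulosa cells (81, lying 278.2 kb upstream), and Fdxr, which supplies electrons to mitochondrial P450 enzymes (80, in intron 2 of 11). These peaks were of middling rank: the median score over the 18 peaks of the list was 58.5, and with only the 618 peaks that scored 99 or more the list no longer passed (2.85-fold, Fisher's exact test, adjusted p = 0.567). With any peak within 50 kb of a gene counted, the excess fell to 3.10-fold (Fisher's exact test, adjusted p = 0.00239). Of the 16 steroidogenesis genes 5 are also in another list, 2 of them in the ovulatory list. Without those 2 genes 8 of 14 were covered (57.1%, 7.58-fold, Fisher's exact test, adjusted p = 1.59e-05), a share below the 59.4% of the ovulatory list. Cholesterol uptake and synthesis had 5 of 20 genes covered, led by Fdft1, which encodes squalene synthase (score 180). Its excess of 3.31-fold passed Fisher's exact test (adjusted p = 0.0339) and did not pass against matched lists (3.05-fold, adjusted p = 0.0826) or with any peak within 50 kb (1.92-fold, adjusted p = 0.139).

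Transcription factors of the granulosa lineage and nuclear receptors were also covered more often than other genes. Of 20 granulosa transcription factors, 11 had a peak (55.0%, exact 95% interval 31.5 to 76.9; 7.30-fold, Fisher's exact test, adjusted p = 3.03e-07; 4.87-fold against matched lists). The best scores were at Epas1, a hypoxia-inducible factor (173), Esr2, the main oestrogen receptor of granulosa cells (139), Runx1 (129) and Hif1a (99). Of these genes 5 are also in the ovulatory list, and without them 6 of 15 were covered (5.30-fold, Fisher's exact test, adjusted p = 0.00172). Of 28 nuclear receptors and coregulators, 11 had a peak (5.21-fold, Fisher's exact test, adjusted p = 1.46e-05; 3.54-fold against matched lists), led by the promoter of Nr1d1, which encodes the clock repressor REV-ERB alpha (221), then Esr2, Nrip1 and Nr4a1. The circadian clock list had 6 of 18 genes covered (4.41-fold, Fisher's exact test, adjusted p = 0.00392; 3.92-fold against matched lists, adjusted p = 0.0130). After Nr1d1 its best scores were at Npas2 (68), Tef (62) and Nfil3 (55), and with peaks at or above the median score alone it no longer passed (2.70-fold, Fisher's exact test, adjusted p = 0.389). With any peak within 50 kb of a gene counted, the excess was 3.03-fold for granulosa factors, 2.56-fold for nuclear receptors and 3.06-fold for the clock (Fisher's exact test, adjusted p = 0.00118, 0.00213 and 0.00176). These lists share genes too: 12 of the 28 nuclear receptors and coregulators, 9 of the 20 granulosa factors and 3 of the 18 clock genes are also in another list.

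Signalling, matrix, cytoskeletal and stress genes made up the remaining lists that passed. In the TGF-beta family 9 of 31 genes had a peak (3.85-fold, Fisher's exact test, adjusted p = 0.00105; 3.03-fold against matched lists, adjusted p = 0.0130). None of its 16 peaks was in the promoter class, and the best were at the receptor gene Acvr1 (264, inside Upp2), Smad3 (237), Id3 (234) and Tgfbr1 (192, inside Col15a1). Within 10 kb of the TSS this list did not pass (2.79-fold, Fisher's exact test, adjusted p = 0.212). Of 24 matrix genes 8 were covered (4.42-fold, Fisher's exact test, adjusted p = 8.69e-04; 3.44-fold against matched lists, adjusted p = 0.00840), led by Tnfaip6, Sdc4 (124), Col4a1 (104) and Ptx3. Within 10 kb of the TSS the matrix list did not pass either (3.61-fold, Fisher's exact test, adjusted p = 0.123). Without the genes it shares with the ovulatory list, Tnfaip6 and Ptx3 among them, 5 of 21 were covered (3.15-fold, Fisher's exact test, adjusted p = 0.0418). Of 27 cytoskeleton and adhesion genes 10 were covered (4.91-fold, Fisher's exact test, adjusted p = 6.61e-05; 4.10-fold against matched lists, adjusted p = 0.00150), with the best scores at Lmna (188), Vim (177), Itgav (151) and Actb (83). With only the peaks that scored 99 or more its call ended (5.08-fold, Fisher's exact test, adjusted p = 0.0569). Of 15 oxidative stress genes 6 were covered (5.30-fold, Fisher's exact test, adjusted p = 0.00141; 4.90-fold against matched lists, adjusted p = 0.00733). The promoter peak of Srxn1, which encodes sulfiredoxin, scored 374, and Nfe2l2, Bach1 and Bach2 followed with 147, 99 and 64. By Fisher's exact test the oxidative stress call ended with peaks at or above the median score (4.87-fold, adjusted p = 0.0548) and with any peak within 50 kb of a gene (2.2-fold, adjusted p = 0.0869), and held with scores of 99 or more (9.15-fold, adjusted p = 0.0148). With any peak within 50 kb counted, the excess was 3.02-fold for the TGF-beta family, 2.29-fold for matrix genes and 2.86-fold for the cytoskeleton (Fisher's exact test, adjusted p = 4.95e-05, 0.0192 and 4.69e-04).

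**Figure D2:**
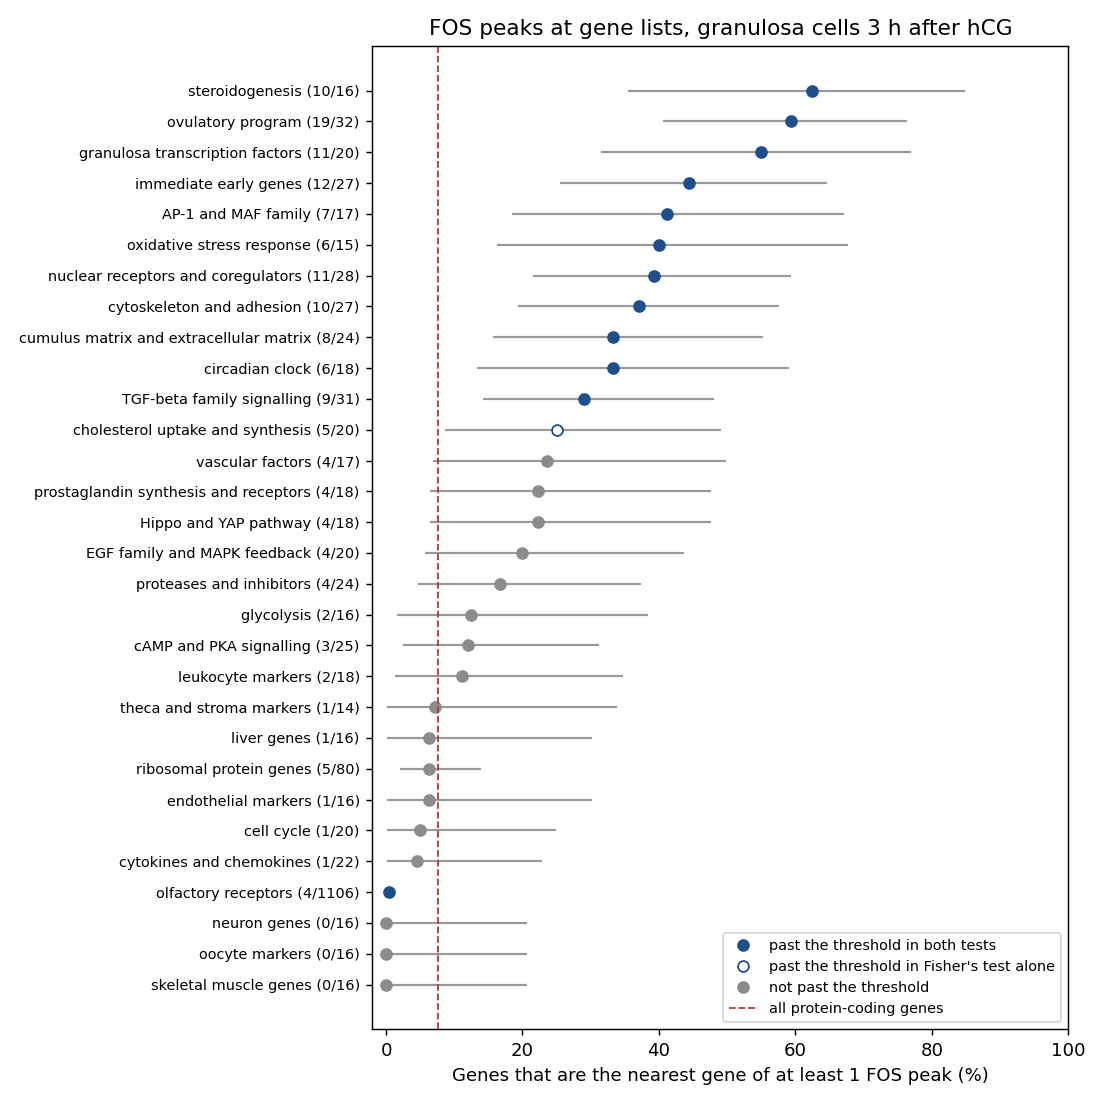
Percent of genes in each of 30 lists that are the nearest gene of at least 1 FOS peak, with exact 95% binomial intervals as bars; the dashed line marks all protein-coding genes (7.58%). The steroidogenesis, ovulatory and granulosa transcription factor lists sit at 62.5%, 59.4% and 55.0%, and the olfactory receptors at 0.362%.

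Several lists tied to ovulation by name did not pass the threshold. Prostaglandin synthesis and receptor genes had peaks at 4 of 18 genes (2.94-fold, Fisher's exact test, adjusted p = 0.0799; 2.33-fold against matched lists), with Abcc4 (66), Ptgis (58), Ptgs2 (44) and Slco2a1 (44). Genes of the EGF family and MAPK feedback had peaks at 4 of 20 (2.64-fold, Fisher's exact test, adjusted p = 0.106; 1.93-fold against matched lists), at Egfr (97), Erbb3 (70), Erbb4 (51) and Dusp5 (37). Vascular factors had peaks at 4 of 17 (3.11-fold, Fisher's exact test, adjusted p = 0.0754; 1.87-fold against matched lists, adjusted p = 0.533), led by Epas1 and Ednra (134). By Fisher's exact test this list passed when peaks were limited to scores of 99 or more (8.07-fold, adjusted p = 0.0190) or to those at or above the median (5.73-fold, adjusted p = 0.0134), and did not pass within 10 kb of the TSS (1.69-fold, adjusted p = 0.761) or without genes of the ovulatory list (1.89-fold, adjusted p = 0.479). The Hippo and YAP list had 4 of 18 covered (2.94-fold, Fisher's exact test, adjusted p = 0.0799; 2.26-fold against matched lists), with Yap1 at 187. Proteases and inhibitors had 4 of 24 (2.2-fold, Fisher's exact test, adjusted p = 0.173; 2.13-fold against matched lists), with Adam10 and Adamts1 both at 124. In cAMP and PKA signalling 3 of 25 genes were covered (1.59-fold, Fisher's exact test, adjusted p = 0.649; 1.13-fold against matched lists), namely Sik1 (109), Crtc3 (78) and Rgs2 (60). When a peak inside a gene was counted for that host gene, 7 of 25 were covered and the list passed (3.54-fold, Fisher's exact test, adjusted p = 0.00657). Pde7b, Creb1, Akap13 and Rapgef4 were the genes gained, each holding a peak assigned to a neighbour. With all annotated genes as the background, calls were gained by the prostaglandin (5.66-fold), EGF and MAPK (5.09-fold), protease (4.24-fold), Hippo (5.66-fold) and vascular (5.99-fold) lists (Fisher's exact test, adjusted p = 0.00879, 0.0123, 0.0225, 0.00879 and 0.00806). Cytokines and chemokines had 1 of 22, an intergenic peak of score 95 at Il1b (0.60-fold, Fisher's exact test, adjusted p = 1; 0.518-fold against matched lists).

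For markers of other ovarian cell types and genes of other tissues, no difference from other genes was detected. Among the marker lists, 1 of 14 theca and stroma genes (Cyp17a1, score 57, inside Wbp1l), 1 of 16 endothelial genes (Flt1, 71), 2 of 18 leukocyte genes (Itgax, 105, and Laptm5, 44) and 0 of 16 oocyte genes had a peak. None of these passed the threshold (Fisher's exact test, adjusted p between 0.803 and 1). Of 16 liver genes Ahsg alone had a peak, and 0 of 16 neuron genes and 0 of 16 skeletal muscle genes had any (adjusted p between 0.803 and 1). No difference was detected either for ribosomal protein, glycolysis and cell cycle genes. Peaks were assigned to 5 of 80 ribosomal protein genes (0.825-fold, Fisher's exact test, adjusted p = 0.999) and 2 of 16 glycolysis genes (1.65-fold, Fisher's exact test, adjusted p = 0.544). Among 20 cell cycle genes 1 was covered, Cdkn1a with a score of 105 (0.660-fold, Fisher's exact test, adjusted p = 1). The olfactory receptor family was the list with a deficit, with 4 of 1106 genes covered (0.362%, 0.0454-fold, Fisher's exact test, adjusted p = 2.69e-31; 0.0743-fold against matched lists). Lists of this size leave wide intervals, such as 0.158% to 30.2% for the endothelial markers, and near-identical receptor genes can lose reads that map to several copies.

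The 10 highest-scoring peaks were not assigned to genes of these lists. The promoter peaks of Srxn1 (374) and Tnfaip6 (355) scored lower, but above the 99th percentile of 307. The top peak, with a score of 2234, lay at chromosome 13, 45623642 to 45624422, in intron 5 of 6 of Atxn1 and was assigned to Gmpr, whose TSS is 116.6 kb away. The next was an intergenic peak of score 1277 at chromosome 17, 65961335 to 65962259, lying 10.6 kb upstream of Twsg1, a modulator of BMP signalling. A peak of score 808 lay in intron 16 of 20 of Nell2 and was assigned to the noncoding gene LOC100043315. Peaks in Kdm1a, the histone demethylase LSD1, in Efr3b (assigned to Pomc) and in Htra3 scored 652, 637 and 577. Those in Jazf1 (assigned to Tax1bp1), in Arhgap28, near Serpinb9c and in Tanc2 (assigned to Cyb561) scored 544, 408, 405 and 400. None of these 10 peaks was in the promoter class. By the authors' gene names, Tomm20, Tns1 and Aff3 each had 5 peaks, and 11 genes had 4, of which Gch1, Gsg1l, Dip2c, Tgif1, Fosl2, Nfia and Arhgap18 had the highest best scores, Arhgap18 level with Slc45a1 at 106. Palm2 and Akap2, which the RefSeq table joins as Pakap, together had 5. The 5 peaks of Tomm20 spread over 122 kb, and the 4 of Gch1, which encodes the entry enzyme of tetrahydrobiopterin synthesis, over 19.5 kb. Of the 1658 protein-coding genes with a peak, 1396 had exactly 1.

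Peaks were spread over all autosomes and nearly missing from the X chromosome. The X chromosome held 15 peaks (0.632%, exact 95% interval 0.354 to 1.04), where its share of protein-coding genes, 4.47%, would give 106. The ratio of observed to expected was 0.141 (exact binomial test, two-sided, adjusted p = 1.21e-27 over 20 chromosomes). Autosomes lay between 0.615 on chromosome 7 and 1.33 on chromosome 10, and 6 of the 19 passed the same test. With the annotated span of each chromosome as the expectation, the ratio for X was 0.0967, chromosome 7 stood at 1.04 and chromosome 11 was highest at 1.56. No peak lay on the Y chromosome. The X peaks in the promoter class were those of Kdm6a (score 131) and Ddx3x (score 66).

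**Figure D3:**
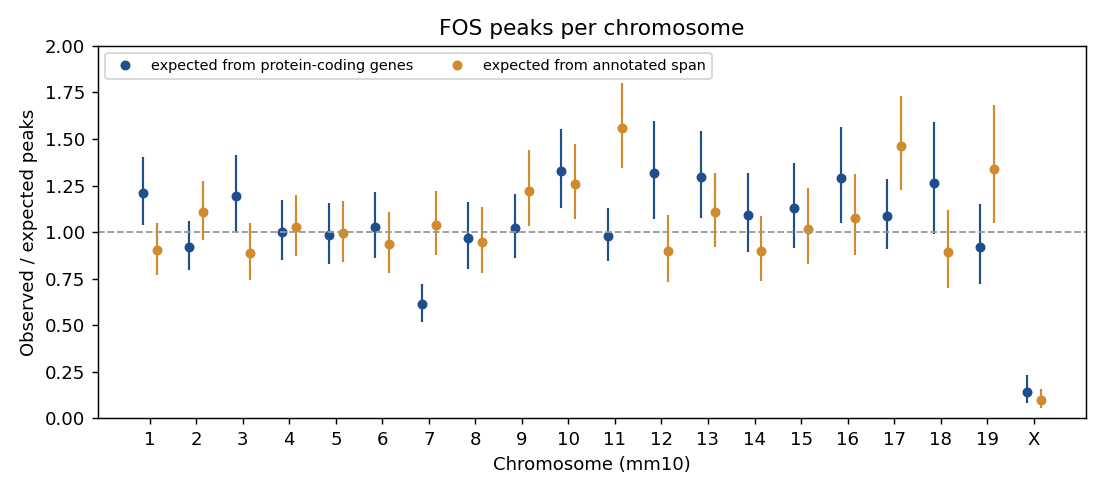
Observed over expected number of FOS peaks on each mm10 chromosome, with the expectation taken from protein-coding genes (blue) or from the annotated span (orange) and bars giving exact 95% binomial intervals. The X chromosome stands at 0.141 and 0.0967, below every autosome on either scale.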

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

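The ovulatory list passed the threshold in all 11 alternatives run on it, with a fold between 3.97 (any peak within 50 kb of the gene span) and 15.2 (all annotated genes as background) and an adjusted p between 1.17e-17 and 9.13e-04. The number of lists with an excess was 12 in the main analysis and between 9 and 17 in the 12 alternatives. The share of promoter peaks depended on its definition: 19.3% of peaks lay within 1 kb of the TSS and 25.3% within 3 kb, against 15.2% in the authors' class. The X ratio was 0.141 in the main analysis, 0.0967 by annotated span and 0.0925 for peaks at or above the median score. Over the other 29 lists, 15 results lost and 8 gained their call and none reversed with a call. Cholesterol uptake and synthesis lost its call in 6 of 12 alternatives, and 5 of the 8 gains (prostaglandin, EGF and MAPK, protease, Hippo and vascular lists) came with all annotated genes as background, a set that adds genes of kinds the lists do not hold. For the remaining changes of call the cause was not tested, although limits on score or distance leave fewer peaks. Over all alternatives the adjusted p ranged from 4.18e-10 to 0.567 for steroidogenesis, 6.77e-06 to 0.0635 for AP-1 and MAF genes, 7.07e-06 to 0.123 for matrix genes, 6.77e-06 to 0.212 for TGF-beta, 1.69e-07 to 0.0569 for the cytoskeleton, 1.13e-04 to 0.567 for the clock, 3.69e-05 to 0.0869 for oxidative stress, 0.00204 to 0.761 for cholesterol, 0.00806 to 0.761 for vascular factors and 0.00657 to 1 for cAMP signalling. Settings that concern the motif search or sequence length were not run. The choices added after seeing the data were host gene assignment, peaks within 50 kb, curated transcripts, removal of the top 1% of scores, removal of genes shared with the ovulatory list and the annotated span. No paired analysis was possible because the series has 1 FOS library, and no replicate could be left out. Depth is unknown, so a gene without a peak is not shown to lack FOS.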

Other observations

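The pooled test of ribosomal protein, glycolysis and cell cycle genes and the tests of host gene assignment and of gene families by symbol root were chosen after the data were seen. The matched test of genes with several peaks was chosen after its unmatched form (42.1% against 15.5%, Fisher's exact test, p = 0.00539). Grouping protein-coding genes by the root of their symbol gave 153 families with at least 15 members, predicted genes left out. The orphan and hormone receptors whose symbols start with Nr had peaks at 8 of 26 genes (4.08-fold, Fisher's exact test, two-sided, adjusted p = 0.0246), namely Nr1d1, Nr1d2, Nr1h4, Nr4a1, Nr4a2, Nr4a3, Nr5a1 and Nr5a2, and this family did not pass against matched lists (3.65-fold, adjusted p = 0.0816). Nr1d1 and Nr4a1 are also in the list of nuclear receptors and coregulators above. Nr1d1 is in the clock list too, Nr4a1 in the immediate early list and Nr5a2 in the steroidogenesis list. Other members may be shared as well, so the result for this family is not independent of those lists. The vomeronasal receptors had peaks at 0 of 355 genes (Fisher's exact test, adjusted p = 6.58e-11; matched lists, adjusted p = 0.0153). Besides these and the olfactory receptors no family passed Fisher's exact test.

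Of the 1135 intron and exon peaks whose host gene was matched, 288 (25.4%) were assigned to another gene, because the annotation takes the nearest TSS. The Tgif1 peaks of score 148 and 142 lie inside Dlgap1, and the peaks of Star, Ptx3 and Cyp17a1 with the best scores lie in Ash2l, Veph1 and Wbp1l. Scores under 26 were held by 100 peaks, scores of 26 to 39 by 309 and scores of 40 to 59 by 547, so the list thins toward its lowest score.

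The first pattern is the excess of peaks at ovulatory genes. Larger territories do not account for all of it, since random lists matched on territory left a 5.95-fold excess. Host gene assignment left 7.15-fold, but it moves 353 of the 2374 peaks and leaves every intergenic peak with the nearest TSS. For this list it left 18 of 32 genes covered in place of 19, so it could hardly test assignment. Counting any peak within 50 kb of a gene, which uses no assignment, left 3.97-fold, down from 7.92-fold and still past the threshold. That count was not matched on territory, so how much of the excess rests on assignment to the nearest TSS stays open. Of the ribosomal protein, glycolysis and cell cycle genes 6.90% (8 of 116) had a peak, against 59.4% of the ovulatory list (Fisher's exact test, p = 7.99e-10, not matched on territory), but no RNA values were used here, so a tendency of FOS to mark any actively transcribed gene stays open. Covered ovulatory genes also held more than 1 peak in 8 of 19 cases, against 3.67 expected among covered genes of like territory (permutation within groups of like territory, two-sided, p = 0.0322). Close peaks were counted separately, such as those of Pgr at 30.9 kb and 31.9 kb upstream, and joining them was not tested. Also open, and untested because only FOS peaks were used, is that chromatin open in granulosa cells around these genes could take peaks of any factor.

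The second pattern is the shortage of peaks on the X chromosome. The ratio of 0.141 is relative to its share of protein-coding genes, so gene number is already allowed for. A weaker signal that falls under the calling threshold, as a single active X in female cells might give, cannot be told apart from other causes. The mean log2 score of X peaks was lower by a difference of -0.29 with a standard error of 0.21 (permutation test, two-sided, p = 0.194, 15 peaks against 2359). That test sees only peaks that passed the threshold, so it cannot show how many fell under it. Of all 2374 peaks 100 scored under 26, near the lowest score of 13, but how the score scales with signal is not stated. How uniquely reads map to X was not tested.

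The third pattern is the few peaks that score far above the rest, up to 2234 in Atxn1 against a 99th percentile of 307. The 23 peaks above that percentile had a median width of 533 bp against 340 bp for the others. If collapsed repeats or an amplified region caused them, neighbouring peaks might be more common, but 4.35% (1 of 23) had another peak within 10 kb against 10.9% of the others (Fisher's exact test, p = 0.503). Nor were they more often promoters, with 13% (3 of 23) against 15.2% (Fisher's exact test, p = 1). A collapsed repeat could also give an isolated peak, so the neighbour test cannot decide on repeats at any number of peaks. For an amplified region and for promoters the peaks are too few to decide. All of these explanations stay open, and no biological explanation was tested.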
